A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

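The series measured total RNA of Schizosaccharomyces pombe on GeneChip arrays that carry probe sets for S. pombe and for another yeast species. Per the labels' protocols, h- cells of either mis4 allele held a plasmid with a res1 fragment under thiamine repression, were released from thiamine to arrest after 7 doublings at 25 °C, and were harvested before and after 2 h at 37 °C. Total RNA came from hot phenol extraction with DNase treatment and column cleanup, and biotin-labelled cRNA was made by a one-cycle kit, per the labels' protocols. The design text of the series says that each strain was grown from 3 independent inoculates, so replicates are biological.

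The authors deposited 1 table of values per array and probe set. Per the submitters' processing notes the values come from RMA, which corrects background, quantile-normalizes all arrays together and summarises the probes of a probe set; its version is not given in the sources used here. RMA gives log2 values, while the deposited values are an intensity on a linear scale, as their range up to 12169 shows; the step back to the linear scale is not stated in the sources used here. All 12 columns were assigned to samples by their names, and 0 columns were left over. Because RMA shares 1 distribution over both species' probe sets and assumes that most signals do not change, a broad shift in S. pombe RNA would be flattened by it, and its summaries of dim probe sets understate fold changes.

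Values were put on the log2 scale without a pseudocount. Of 10928 probe sets, 2914 were annotated to 1 gene that the reference table of S. pombe (assembly ASM294v3) holds, 20 to several genes, 2601 to 1 gene with an upper-case name that is not in that table, and 3 to names that matched nothing; 213 were controls, and 5177 had no gene name here and stayed out of the gene tests. Symbols were updated through the gene identifier for 110 genes. Where a gene had more than 1 probe set (14 genes), the brightest over all arrays was used, which left 2896 genes; 13 of these are read by a probe set marked as shared between sequences. The 95th percentile of the 12-array means of the 2601 probe sets served as the background level, at 3.42 on the log2 scale (an intensity of 10.7), and 2879 genes lay above it in at least 1 group. Arrays give no read depth, and their number limits the precision.

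Comparisons were made in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit, eBayes with default settings) in 1 fit of the 4 group means over all 12 arrays, with no block and no intensity filter. They were mis4-367 against mis4+ at 37 °C and at 25 °C, 37 °C against 25 °C in each strain, and the difference between the temperature responses. Adjusted p-values are Benjamini-Hochberg values over the 2896 genes of a comparison, and genes with adjusted p under 0.05 are said to have changed, risen or fallen. Figures were drawn with matplotlib 3.10.9.

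Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 19 lists with at least 5 measured genes, and again with the correlation estimated per list; every call made with the preset correlation was lost with the estimated one. The self-contained test fry was an alternative. For the strains at 37 °C it gave adjusted p = 0.024 for mating and for meiotic genes and 0.0285 for mitosis and septation. Iron and ribosomal protein genes had 0.0623 in fry, and ribosome biogenesis 0.307. At 25 °C the smallest fry value was 0.151, and for the difference of temperature responses 0.897. For the shift, lists called by camera had fry values of at most 5.39e-05, except ribosomal proteins in mis4+ (0.0556). Several lists not called by camera also had fry adjusted p under 0.05 for the shift. The smallest were those of heat shock proteins, 7.4e-06 in mis4+ and 8.93e-06 in mis4-367. Lists covered heat shock proteins, the core environmental stress response, MBF targets, histones, cohesin, heterochromatin and telomere silencing, ribosomal proteins, ribosome biogenesis, iron, mating with nitrogen starvation, meiosis, thiamine, hexoses with gluconeogenesis, mitosis and septation, cell wall, DNA replication and repair, the proteasome, subtelomeric genes and genes next to the ends of chromosome III (20 per end, of which 13 were measured). Phosphate-regulated genes (4 measured) and flocculin-like glycoproteins (3 measured) were too few for camera, and of Tf2 retrotransposons 0 were measured. Some measured members have other known functions: mak1, mak2, mak3, imp1 and imp2 in the ribosome biogenesis list and ryh1 in the cohesin list. The iron list also holds the copper genes ctr4, ctr5, ctr6 and cuf1, and was not run without them. Subtelomeric genes were the 40 outermost protein-coding genes at each of the 4 ends of chromosomes I and II by gene order in the reference table, and their share of changed genes was set against that of all other measured genes by two-sided Fisher's exact test. A comparison of convergent with tandem gene pairs was planned and not run, since the reference table has no strand.

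Genes were named by a rule fixed before the data were examined, as were the groups, the tests, the lists and most alternatives. For each comparison of strains it took the 10 genes with the largest rise and the 10 with the largest fall among genes with adjusted p under 0.05, with groups that did not overlap over replicates and a brighter group mean above background (5 each for the other comparisons). It added mis4, res1, cdc10, rad21, psm1, psm3, psc3, ssl3, tlh1 and tlh2, up to 4 passing members of each list that passed camera or had passing members, and the member with the largest change from other lists. Of the fixed genes, tlh1 has no probe set named here.

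The samples taken before and after the shift share cultures, per the design text, so the temperature comparisons were also fitted with the culture as a block. That the same replicate number marks the same culture at both temperatures is inferred from the numbers and stated by no source used here. Deviations of same-numbered arrays of a strain from their group means correlated weakly across genes, with r = -0.07, 0.03 and -0.09 in mis4+ and 0.07, 0.06 and 0.09 in mis4-367, and the block changed no count of genes by more than 1.5 times.

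Alternatives were a filter on dim probe sets, re-centring of each array on its median over the S. pombe genes, quantile normalization over those genes, the mean of all probe sets of a gene, eBayes with trend and robust settings, only the compared groups in the fit, a replicate block, fold limits of 1.5 and 2, other numbers of outermost genes, and leaving out each array of the compared groups in turn. Array weights, the unnamed probe sets joined to the genes, corrected lists, fits without the third arrays at 37 °C and the strain effect averaged over temperatures were added after the data had been seen. So was leaving out 1 array for the lists and for the correlations of effects.

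The fit was tested on simulated data drawn for the 2896 genes with 200 changed, in 5 runs per comparison. For the comparison of strains at 37 °C it recovered 80.9% of changes of 0.3 on the log2 scale, 99.4% of 1.5-fold and 100% of 2-fold changes, with 4% false calls. For the same comparison at 25 °C the shares were 81%, 99.6% and 100%, with 4.4% false calls. The difference of the temperature responses gave 36.8%, 94% and 100%, with 3.4% false calls, and the shift gave 77%, 99.2% and 100% in mis4+ and 79.4%, 99.4% and 100% in mis4-367, with 5.6% and 3.5% false calls. Simulated genes were drawn independently, so these shares do not cover an array that departs as a whole. Each simulated gene also had 1 spread for all 4 groups, so the shares do not cover groups of unequal spread. In the data, arrays at 37 °C differed from the others of their group with SDs over genes of 0.091 to 0.202. At 25 °C these SDs were 0.065 to 0.103.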

Results

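RNA levels were measured on oligonucleotide arrays in fission yeast (Schizosaccharomyces pombe) cells that had been arrested in G1, the phase before DNA replication. The cells carried either the wild-type allele mis4+ or the thermosensitive allele mis4-367. Mis4 loads cohesin, the ring-shaped protein complex that holds sister chromatids together and shapes chromosomes, onto DNA. The series addresses which genes depend on cohesin for their expression. Arrest was obtained by overproducing a C-terminal fragment of Res1, a partner of the transcription factor Cdc10, from a plasmid that thiamine represses. Cells stopped dividing after 7 doublings without thiamine at 25 °C and were then moved to 37 °C for 2 h. Arrays of 3 independent cultures per strain, taken before and after the shift, gave 12 arrays in 4 groups of 3, and all fold changes compare group means of 3 arrays unless stated. Each of 2896 genes was read from 1 probe set, which covers part of the 5113 protein-coding genes of the reference table. The number of arrays limits the precision: the median standard error of a log2 difference between groups was 0.065.

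The arrays were similar in brightness, with median intensities over the S. pombe genes of 394 to 433. Principal component 1 (80.5% of the variance) separated 25 °C from 37 °C, and component 2 (9.2%) ordered the strains, with mis4+ above mis4-367 at each temperature. Replicate 3 of mis4+ at 37 °C lay apart on component 2, at 9.95, where the other 11 arrays lay between -4.41 and 2.48. Its log2 values differed from the mean of the other arrays of its group with an SD over genes of 0.20, against 0.065 to 0.134 for every other array.

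**Figure D1:**
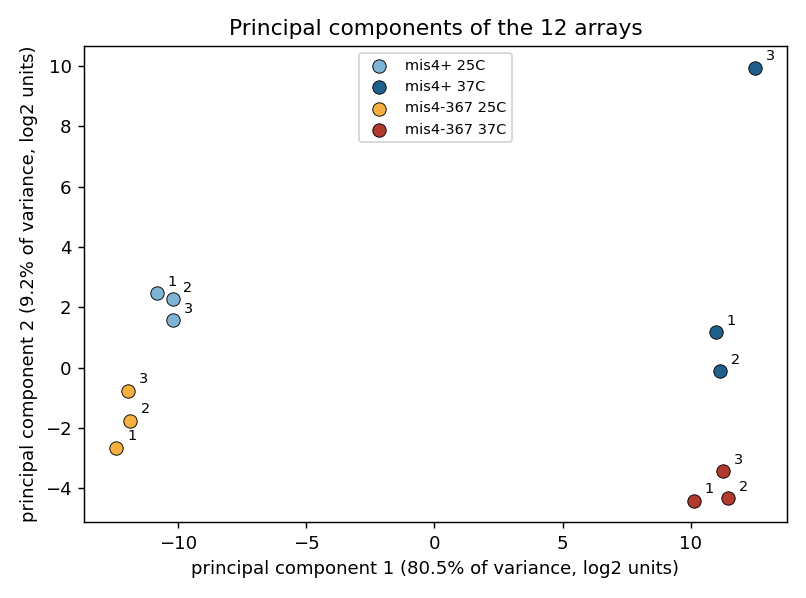
Scores of the 12 arrays on principal components 1 and 2 of the log2 values, in log2 units, with 1 point per array, colour for the group and the replicate number beside each point. Temperature parts the arrays along component 1, and mis4+ replicate 3 at 37 °C sits at 9.95 on component 2.

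The transcript of mis4 itself did not differ between the strains by more than the spread between arrays. At 37 °C its log2 value was 8.26 ± 0.13 (SD, n = 3) in mis4-367 and 8.32 ± 0.08 (SD, n = 3) in mis4+, a change of -0.07 (adjusted p = 0.541), and at 25 °C the change was -0.13 (adjusted p = 0.525). An allele that impairs the protein at high temperature need not change its mRNA, so this level is no check of the strain labels. The shift raised mis4 in both strains, by 1.21-fold in mis4+ (adjusted p = 0.00531) and 1.26-fold in mis4-367 (adjusted p = 0.00142). Whether the probe set of res1 lies in the fragment on the plasmid that imposed the arrest is not given in the sources used here, so its signal is no measure of the arrest. It was 1.32-fold higher in mis4-367 than in mis4+ at 37 °C (log2 change 0.40 ± 0.09, SE, adjusted p = 0.0318). Before the shift the strains differed in res1 by 1.12-fold (adjusted p = 0.558). The shift lowered res1 in mis4+, by -0.46 on the log2 scale (adjusted p = 0.00118), while in mis4-367 the change was -0.22 (adjusted p = 0.06). The difference between these responses, 0.24, did not pass its own test (adjusted p = 0.824). The strain difference of res1 at 37 °C had adjusted p from 0.0543 to 0.123 when replicate 1 or 3 of mis4+ or replicate 2 or 3 of mis4-367 was left out.

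At 37 °C, the restrictive temperature, more genes were lower than higher in mis4-367 cells on the deposited scale (158 against 50), mostly by modest amounts, whereas quantile normalization over the S. pombe genes gave 88 of each and re-centring 108 lower and 80 higher. Quantile normalization gives every array the same distribution, and re-centring the same median. Both tend to even the directions by construction, so they cannot decide the direction. Some members of the mating, meiotic, mitosis and iron lists were lower (9 of 29, 4 of 43, 5 of 26 and 2 of 16). The camera calls of these 4 lists were lost with an estimated correlation (adjusted p from 0.716 to 0.785). Of the 2896 genes, 158 were lower and 50 higher in mis4-367 (208 in all, limma, adjusted p under 0.05). An unadjusted p under 0.05 was found for 850, where chance gives 144.8 if the spread shared by all groups holds at 37 °C. Arrays differed from the others of their group with SDs over genes of 0.091 to 0.202 at 37 °C. At 25 °C these SDs were 0.065 to 0.103. The shared spread may therefore give too many calls at 37 °C. With only the compared groups in the fit, 10 genes passed. The median size of the 208 changes was 0.29 on the log2 scale. Only 7 reached 1.5-fold, all lower: str3, mfm1, frp1, spn6, mfm3, but1 and caf5. The lowest was str3, a transporter gene of iron and heme supply, at -1.14 ± 0.24 (SE), or 2.2-fold (adjusted p = 0.0253). Next came mfm1, which encodes a precursor of the M-factor mating pheromone, at -0.89 ± 0.13 (1.86-fold, adjusted p = 0.00513). The ferric reductase gene frp1 fell by 0.64 (adjusted p = 0.0253) and spn6, a septin gene, fell by 0.63 (adjusted p = 0.00517).

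Higher levels in mis4-367 at 37 °C were found for aes1 (0.58 ± 0.07, SE, 1.49-fold, adjusted p = 0.00298), for tim10 (0.49) and tim9 (0.39), which encode chaperones of mitochondrial import, and for sub1 (0.49) and dss1 (0.49). The other genes among the 10 with the largest rise were res1, ppp1 (0.38), uba2 (0.37), its8 (0.34) and nup107 (0.34). The level of aes1 was 9.11 ± 0.03 (SD, n = 3) in mis4-367 and 8.53 ± 0.10 (SD, n = 3) in mis4+, and the strains stood at 9.07 and 9.04 before the shift.

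The list of mating, pheromone response and nitrogen starvation genes had the lowest median change of the 19 lists at 37 °C. Of 29 measured members, 9 fell in mis4-367 at 37 °C, none rose and 20 did not pass; adjusted over the list alone, 14 fell. Besides mfm1, the members that fell furthest were mfm3, a second M-factor gene (-0.62 ± 0.08, SE, adjusted p = 0.00288), ste11, the transcription factor that starts sexual differentiation (-0.53 ± 0.13, adjusted p = 0.0342), and byr2, a kinase of the pheromone response (-0.46 ± 0.05, adjusted p = 0.00288). The list had a median change of -0.25, and 27 of its 29 members lay below 0. It stood below the other genes in camera with a preset correlation (adjusted p = 3.43e-05), a call that was lost with adjusted p = 0.716 with an estimated correlation. The same list deviated by a median of 0.21 on the array of mis4+ replicate 3 at 37 °C, and without that array its median was -0.17. The call of ste11 was lost without that array or without any 1 of the 3 arrays of mis4-367 at 37 °C (adjusted p from 0.059 to 0.123).

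Of 43 meiotic genes measured, 4 fell, none rose and 39 did not pass (adjusted over the list alone, 13 fell), among them meu13 (-0.52) and dmc1 (-0.43) of meiotic recombination, rec10 (-0.52) of the linear elements that form along meiotic chromosomes, and meu14 (-0.41) of the forespore membrane. Their median was -0.18 (camera adjusted p = 0.00262, adjusted p = 0.716 with an estimated correlation), and the call was also lost after quantile normalization (median -0.042, adjusted p = 0.545).

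Of 26 genes of mitosis and septation, included as markers of cells outside G1, 5 fell, none rose and 21 did not pass (adjusted over the list alone, 6 fell). They included slp1, an activator of the anaphase-promoting complex (-0.50 ± 0.06, SE, adjusted p = 0.00288), the mitotic kinase gene fin1 (-0.43), the B-type cyclin gene cdc13 (-0.32) and the phosphatase gene cdc25 (-0.27). The list median was -0.15 (camera adjusted p = 0.0106, adjusted p = 0.716 with an estimated correlation). On the array of mis4+ replicate 3 at 37 °C these genes deviated by a median of 0.17, and without that array the list median was -0.089. After quantile normalization it was -0.094. Of the 19 measured targets of MBF, the Cdc10-Res complex, whi5 fell (-0.23) and 18 did not pass (adjusted over the list alone, none passed, and camera gave adjusted p = 0.417). Among 11 histone genes hta2 (-0.33) and cnp1 (-0.28), the centromeric histone H3 gene, fell (adjusted over the list alone, 2 fell and 1 rose; camera adjusted p = 0.849).

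Iron genes were represented by a list of 16 members, some of them copper genes, of which str3 and frp1 fell and 14 did not pass (adjusted over the list alone, 4 fell). The list median was -0.18 (-0.12 without replicate 3 of mis4+ at 37 °C), with 15 of 16 members below 0 (camera adjusted p = 0.0311, adjusted p = 0.785 with an estimated correlation). The camera call was lost without replicate 2 of mis4+ (adjusted p = 0.322) or without replicate 3 of mis4-367 (adjusted p = 0.154) at 37 °C. Replicates of str3 in mis4+ at 37 °C were far apart, at 6.07 ± 0.53 (SD, n = 3), and the calls of str3 and frp1 were lost without replicate 3 of mis4+ (adjusted p = 0.0541 and 0.059) or without replicate 2 (0.0758 and 0.0679) or 3 (0.059 and 0.0598) of mis4-367.

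Ribosomal protein genes were almost level between the strains. Of the 118 cytosolic ribosomal protein genes none passed at 37 °C, over all genes or adjusted over the list alone, and their median of 0.034 stood slightly above that of the other genes, which was below 0 (camera adjusted p = 2.72e-07, adjusted p = 0.635 with an estimated correlation). After quantile normalization that call was lost (adjusted p = 0.336), and without replicate 1 of mis4+ at 37 °C the median was 0.020. Of 46 ribosome biogenesis factors spb1 (0.33) and noc3 (0.17) rose and 44 did not pass (median 0.03, camera adjusted p = 0.00256, adjusted p = 0.716 with an estimated correlation). Adjusted over the list alone 2 rose, and without replicate 2 of mis4+ at 37 °C the camera call was lost (adjusted p = 0.0862) and the median was -0.009. Without replicate 3 of mis4+ it was 0.059, and without replicate 3 of mis4-367 0.018.

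The remaining lists did not pass camera at 37 °C. In cell wall and glucan synthesis, exg2 (-0.33) and the alpha-glucan synthase genes mok12 (-0.31) and ags1 (-0.25) fell among 22 members (adjusted p = 0.0717). Among 27 heterochromatin and telomere silencing factors the telomere protein gene rap1 (-0.31) and the deacetylase gene sir2 (-0.19) fell (adjusted p = 0.272). The core environmental stress list had ish1 (-0.25) and tps1 (-0.16) lower among 29 (adjusted p = 0.849), the heat shock list psi1 (-0.18) among 17 (adjusted p = 0.849), and DNA replication and repair cdc1 (-0.27) among 30 (adjusted p = 0.27). Adjusted over the list alone, 2 core stress genes rose and 5 fell. In the same way 4 cell wall, 3 heterochromatin and telomere silencing, 2 heat shock and 4 DNA replication and repair genes fell, and none rose. Of 17 cohesin subunits and regulators only the securin gene cut2 fell (-0.25, adjusted p = 0.0455), and none passed adjusted over the list alone (camera adjusted p = 0.849). The cohesin core gene psm1 was at -0.31 (adjusted p = 0.0718), psm3 at -0.15 (adjusted p = 0.124), rad21 at -0.01, psc3 at -0.01, and ssl3, the partner of Mis4 in the loader, at 0.00. No member passed among 12 thiamine-regulated genes, 25 genes of hexose transport and gluconeogenesis, 26 proteasome genes or 13 genes next to the ends of chromosome III (camera adjusted p = 0.849 for each).

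**Figure D2:**
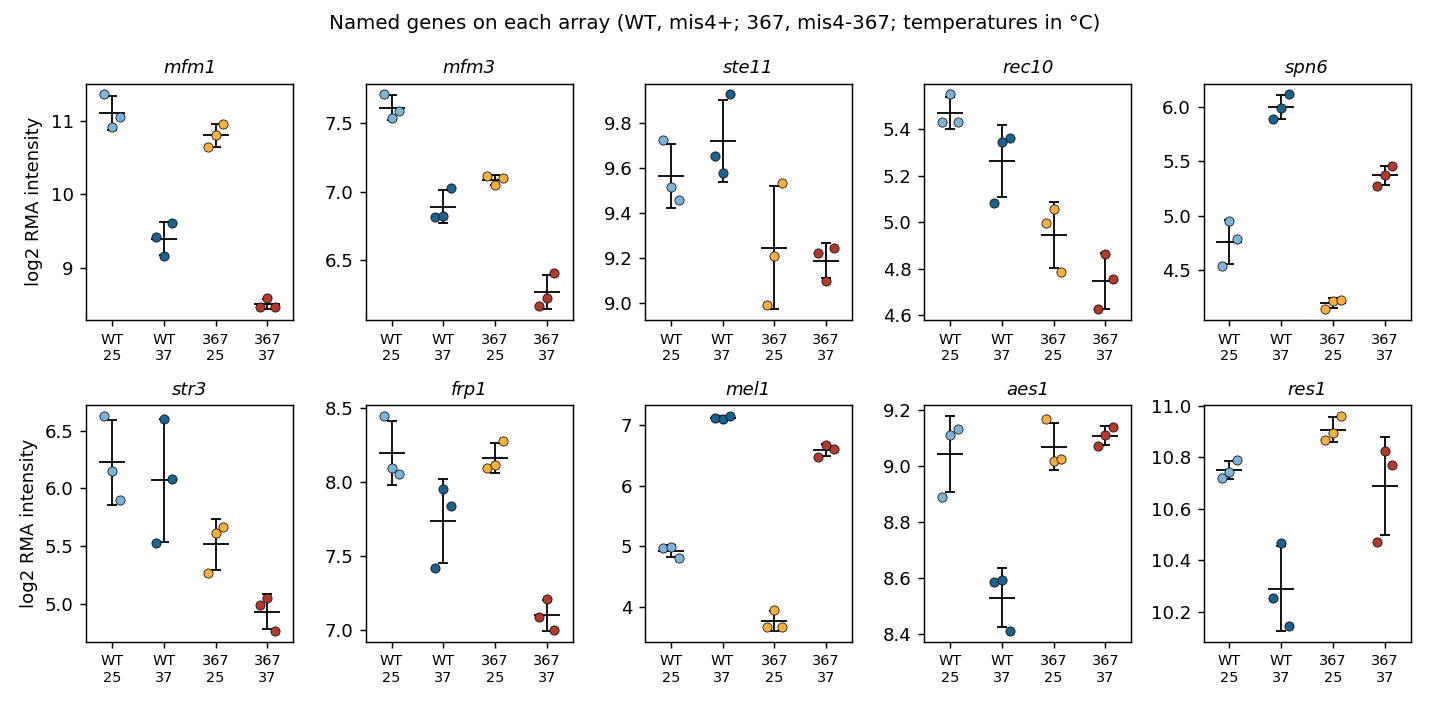
Log2 RMA intensity of 10 named genes on each of the 12 arrays, with points for arrays, a horizontal bar for the mean of 3 and a vertical bar for 1 SD. At 37 °C mfm1, mfm3, ste11, rec10, spn6, str3, frp1 and mel1 are lower in mis4-367 than in mis4+, and aes1 and res1 are higher.

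The count of 208 depended on the spread that the groups shared, and it moved with most of the arrays left out. It was 103 without replicate 3 of mis4+ at 37 °C, 566 without its replicate 2, 195 without its replicate 1, and 121, 22 and 92 without replicate 1, 2 or 3 of mis4-367 at 37 °C; with only the 6 arrays at 37 °C in the fit it was 10. Of 43 named genes that passed, 11 did so with each array of the 2 groups compared left out in turn: aes1, uba2, mfm1, spn6, mfm3, but1, mel1, byr2, rec10, slp1 and cdc1. Under re-centring, quantile normalization, the mean of all probe sets and the replicate block, 29 of the 43 kept their call in each. 

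Genes near the chromosome ends were examined apart. Of the 160 outermost genes at the 4 ends of chromosomes I and II, 40 per end, 32 were measured, meaning read by a probe set with a gene name here. With 20 genes per end, 8 were measured. Any subtelomeric gene read only by the 5177 probe sets without a gene name was left out. The tests below therefore cover a small part of these regions and cannot speak for the rest. At 37 °C aes1 was higher in mis4-367, and str3 and mel1, an alpha-galactosidase gene (-0.53 ± 0.08, SE, adjusted p = 0.00517), were lower, which is 9.4% of the measured subtelomeric genes against 7.2% of all other measured genes (Fisher's exact test, two-sided, p = 0.498; odds ratio 1.34). The list median was -0.086 against -0.046 for the other genes, and camera gave adjusted p = 0.849. Adjusted over the list alone, 1 rose and 5 fell. The telomere-linked helicase gene tlh2, the outermost measured gene of its end, was at -0.23 (adjusted p = 0.0732), on a probe set marked as shared between sequences, and tlh1 was not analysed here. Without replicate 2 of mis4-367 at 37 °C, when 22 genes passed in all, Fisher's exact test gave p = 0.0238.

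At 25 °C, the permissive temperature, the strains already differed in some of the same genes. In mis4-367, 18 genes were lower and none higher than in mis4+. An unadjusted p under 0.05 was found for 329, against 144.8 from chance if the shared spread holds at 25 °C. The alpha-galactosidase gene mel1 changed most, at -1.15 ± 0.08 (SE), or 2.22-fold (adjusted p = 1.58e-05): it stood at 3.77 ± 0.16 (SD, n = 3) in mis4-367 and 4.93 ± 0.10 (SD, n = 3) in mis4+. The meiotic gene meu10 was at -0.63 ± 0.12 (adjusted p = 0.042), and but1 (-0.57), spn6 (-0.56), the pheromone gene mfm3 (-0.53), rec10 (-0.53), tms1 (-0.48), mcp4 (-0.46), duo1 (-0.45) and ppk33 (-0.38) made up the 10 that fell furthest. Of 43 meiotic genes meu10 and rec10 fell (adjusted over the list alone, 9 fell; median -0.12, camera adjusted p = 0.00603, adjusted p = 0.733 with an estimated correlation). Among 29 mating and nitrogen starvation genes mfm3 fell (adjusted over the list alone, 3 fell; median -0.12, camera adjusted p = 0.0358, adjusted p = 0.733 with an estimated correlation). In the core environmental stress list tms1 and ish1 (-0.32) fell (adjusted over the list alone, 4 fell; camera adjusted p = 0.579).

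Heterochromatin and telomere silencing factors had no member past the test at 25 °C (adjusted over the list alone, 2 fell), with a list median of -0.089 (camera adjusted p = 0.0358, adjusted p = 0.733 with an estimated correlation). Ribosomal protein genes had none either, over all genes or adjusted over the list alone, and 101 of 118 lay above 0 at a median of 0.028 (camera adjusted p = 6.16e-12, adjusted p = 0.206 with an estimated correlation). After quantile normalization all 4 of these list calls were lost, with adjusted p = 0.164 for mating (median -0.048) and 0.529 for meiotic (-0.019), heterochromatin (-0.004) and ribosomal protein genes (0.005). The mating call was also lost without replicate 1 of mis4+ (adjusted p = 0.138) or of mis4-367 (adjusted p = 0.442, list median -0.080), the meiotic call without replicate 1 of mis4-367 (adjusted p = 0.0747), and the heterochromatin call without replicate 1 or 3 of either strain (adjusted p from 0.0541 to 0.078). Of the 32 subtelomeric genes only mel1 fell, 3.1% against 0.6% of the other genes (Fisher's exact test, two-sided, p = 0.182).

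The count at 25 °C depended on the spread that the 4 groups shared, on the scaling and on single arrays. With only the 6 arrays at 25 °C in the fit, 154 genes passed (14 higher, 140 lower), and with the third array of mis4+ at 37 °C out of the fit 102 passed (5 higher, 97 lower), each including all 18. Quantile normalization left 3 genes, and leaving out 1 array at a time left 5 (mis4+ replicate 2 or 3, or mis4-367 replicate 1), 7 (mis4-367 replicate 2), 11 (mis4+ replicate 1) or 14 (mis4-367 replicate 3). Of 11 named genes that passed, mel1, but1, mfm3 and tms1 did so with each array of the 2 groups compared left out in turn. Under re-centring, quantile normalization, the mean of all probe sets and the replicate block, 3 of the 11 kept their call in each.

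Strain effects at the 2 temperatures were related. Across the 2896 genes, which are not independent replicates, Pearson's r between them was 0.561 and Spearman's rho 0.56; the arrays differed, although each culture was sampled at both temperatures, per the design text. Of the 208 genes that changed at 37 °C, 199 had the same sign at 25 °C, as had all 18 of the genes that changed at 25 °C. The calls shared 12 genes, all lower, where independent lists would share 1 in the same direction.

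**Figure D3:**
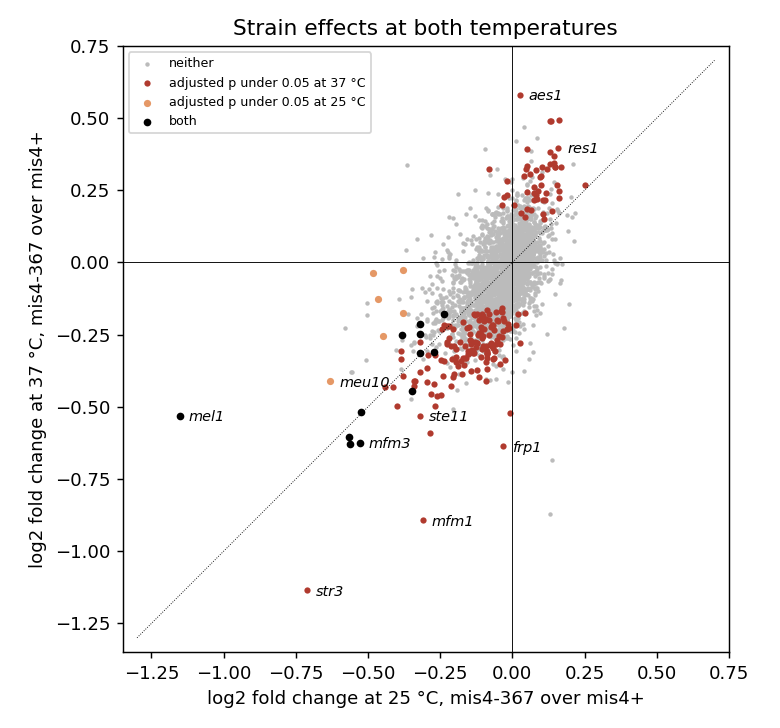
Log2 fold change of mis4-367 over mis4+ at 37 °C (vertical) against 25 °C (horizontal), with 1 point per gene and colour for the temperatures at which its adjusted p was under 0.05; the dotted line marks equal changes. Of the 208 genes that passed at 37 °C, 199 lie on the same side of 0 at 25 °C.

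Far more genes changed with the shift to 37 °C than differed between the strains. In mis4+ 968 genes rose and 633 fell (1601 in all, 295 at least 1.5-fold and 85 at least 2-fold), and in mis4-367 966 rose and 667 fell (1633 in all, 326 and 97). In mis4+ the largest rises were in say1 (3.40 ± 0.17, SE, 10.6-fold, adjusted p = 1.52e-08), the kinase gene ppk31 (2.82), the meiotic gene hop1 (2.62), spk1, a MAP kinase of the pheromone response (2.55), and the septin gene spn5 (2.39). The largest falls were in gut2, a glycerol-3-phosphate dehydrogenase gene (-2.81 ± 0.07, 7.01-fold, adjusted p = 4.96e-11), the invertase gene inv1 (-2.47), the phosphatase gene pyp2 (-2.17), urg2 (-2.00) and oca2 (-1.77). In mis4-367 say1 (3.76), mel1 (2.81), tms1 (2.75), ppk31 (2.73) and hop1 (2.52) rose most, and gut2 (-2.80), inv1 (-2.39), mfm1 (-2.30), urg2 (-2.10) and pyp2 (-2.06) fell most.

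With the shift, 29 of 43 meiotic genes rose and 4 fell in mis4+, among them mcp7 (2.12), rec15 (1.73) and mug4 (1.58), with a list median of 0.39 (camera adjusted p = 0.00252, adjusted p = 0.585 with an estimated correlation). In mis4-367 25 rose and 2 fell, with a median of 0.31 (camera adjusted p = 0.0146, adjusted p = 0.88 with an estimated correlation). Adjusted over the list alone, 29 rose and 5 fell in mis4+, and 25 rose and 2 fell in mis4-367. After quantile normalization the medians were 0.123 and 0.104, and the camera calls were lost (adjusted p = 0.45 and 0.621). The mating list split instead: in mis4+ 13 rose and 9 fell of 29, with spk1 up and mfm1 (-1.72), isp7 (-1.21) and isp5 (-1.14) down (camera adjusted p = 0.997), and in mis4-367 12 rose and 11 fell (camera adjusted p = 0.664). Adjusted over the list alone these were 13 and 11 in mis4+ and 12 and 11 in mis4-367.

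Of 17 heat shock and chaperone genes, 11 rose and 2 fell in mis4+, led by cdc37 (0.84), hsp16 (0.83), hsp10 (0.51) and psi1 (0.45). In mis4-367 11 rose, with hsp16 at 1.10 and cdc37 at 0.84, and 3 fell, with ssa1 at -0.77. The list did not pass camera (adjusted p = 0.0616 in mis4+ and 0.226 in mis4-367), and adjusted over the list alone 11 rose in each strain while 2 fell in mis4+ and 4 in mis4-367. The self-contained test fry, which does not set the list against other genes, gave adjusted p = 7.4e-06 in mis4+ and 8.93e-06 in mis4-367. The core environmental stress list went both ways, with 13 up and 12 down of 29 in mis4+ and 14 up and 11 down in mis4-367. There tms1 (2.30 in mis4+) and sro1 (1.48) rose while pyp2 and ish1 (-1.64) fell (camera adjusted p = 0.515 and 0.532).

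The list of heterochromatin and telomere silencing factors did not pass camera for the shift, while fry gave adjusted p = 0.0148 in mis4+ and 0.0157 in mis4-367. Of its 27 members 16 rose and 11 did not pass in mis4+, with rik1 (0.77), ago1 (0.61), rdp1 (0.54) and mit1 (0.46) rising most, and 14 rose and 13 did not pass in mis4-367, with rik1 at 0.92 (camera adjusted p = 0.0569 and 0.0763; adjusted over the list alone, the same counts of 16 and 14). On the array of mis4+ replicate 3 at 37 °C these genes deviated by a median of 0.22. Of 118 ribosomal protein genes 5 rose and 19 fell in mis4+ (adjusted over the list alone, 2 rose and 10 fell; median -0.028, camera adjusted p = 0.0278, adjusted p = 0.85 with an estimated correlation), and 4 rose and 13 fell in mis4-367 (adjusted over the list alone, 3 rose and 6 fell; camera adjusted p = 0.0751). The call in mis4+ was lost after quantile normalization (adjusted p = 0.37) and without replicate 3 at 25 °C (adjusted p = 0.0571) or replicate 1 at 37 °C (adjusted p = 0.0594, median -0.018).

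The measured subtelomeric genes changed with the shift more often than the other measured genes in mis4+. There 20 of the 32 rose and 6 fell, 81.2% against 55% of all other measured genes (Fisher's exact test, two-sided, p = 0.00353), with say1, mel1 (2.19), the galactose gene gal10 (1.81) and pcm2 (1.77) rising most. In mis4-367 19 rose and 4 fell, 71.9% against 56.2% (Fisher's exact test, two-sided, p = 0.105), with mug14 at 1.88 and the proline permease gene put4 at -1.82. The medians were 0.36 and 0.29 (camera adjusted p = 0.0278 and 0.0279, adjusted p = 0.585 and 0.88 with an estimated correlation; adjusted over the list alone, 20 rose and 6 fell in mis4+ and 19 rose and 5 fell in mis4-367). For mis4+ both calls were lost after quantile normalization (Fisher's exact test p = 0.149, camera adjusted p = 0.259), the camera call without replicate 2 at 37 °C (adjusted p = 0.0753), and the exact test with 20 genes per end (p = 0.0822). In mis4-367 the camera call was lost after quantile normalization (adjusted p = 0.142) and without replicate 1 at 37 °C (adjusted p = 0.0564). Of the 13 genes next to the ends of chromosome III, 3 rose and 4 fell in mis4+, with the catalase gene ctt1 at -0.92 (camera adjusted p = 0.428).

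Hexose transport and gluconeogenesis had 6 up and 8 down of 25 in mis4+, with gal10 and gal1 (1.49) up and gut2 and inv1 down (camera adjusted p = 0.499). Iron uptake had 5 up and 5 down of 16 in mis4+ and 1 up and 5 down in mis4-367, with sib1 of siderophore synthesis at 0.98 and the transporter gene str1 at -0.72 in mis4+ (camera adjusted p = 0.835 and 0.412). The 4 measured phosphate-regulated genes were too few for camera, and nc-pho1 (1.08), gde1 (0.81) and csk1 (0.43) rose in mis4+. Of the 3 measured flocculin-like genes mam3 (1.13) and map4 (0.34) rose.

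**Figure D4:**
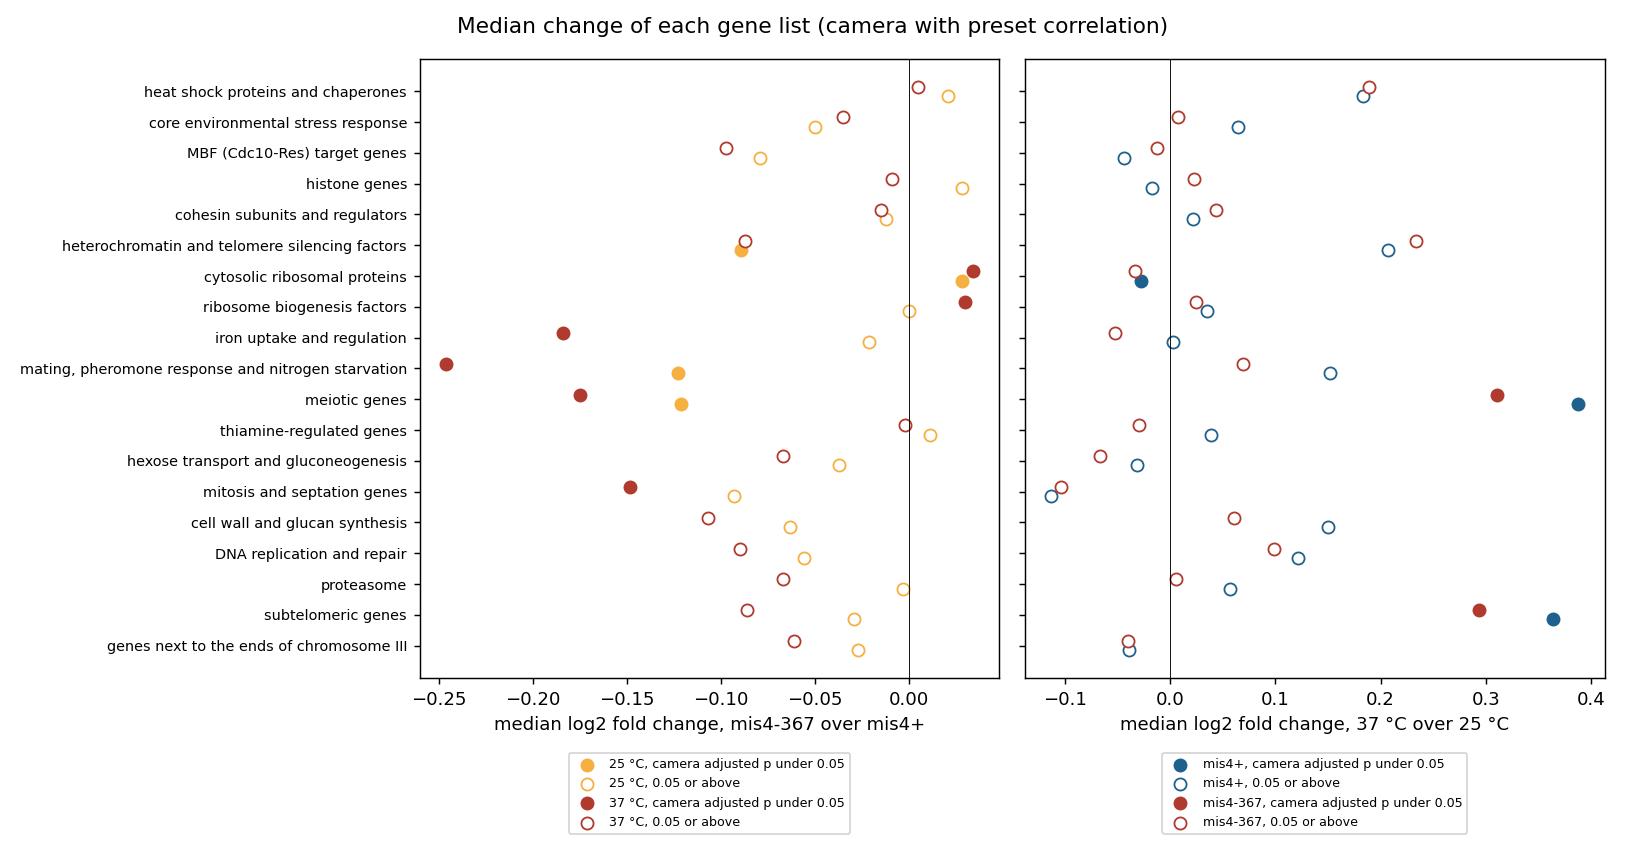
Median log2 fold change of each of 19 gene lists for mis4-367 over mis4+ (left) and for 37 °C over 25 °C (right), with 1 point per list and comparison; filled points have a camera adjusted p under 0.05 with the preset correlation. Mating genes have the lowest median between strains at 37 °C (-0.25), and meiotic genes the highest for the shift in mis4+ (0.39), on the deposited scale; after quantile normalization the meiotic median (0.123) lay below that of subtelomeric genes (0.185).

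The temperature responses of the 2 strains were close to each other. Across genes they correlated with Pearson's r of 0.959 and Spearman's rho of 0.931. The calls shared 1350 genes that moved in the same direction, where independent lists would share 468.7 in the same direction, and 1586 of the 1601 genes called in mis4+ had the same sign in mis4-367. Quantile normalization evened the directions, which it tends to do by construction, to 847 higher and 834 lower in mis4+ and 828 and 837 in mis4-367.

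No gene passed the test of the difference between the temperature responses (limma, 2896 genes, smallest adjusted p = 0.125). At an unadjusted p under 0.05 there were 141, where chance gives 144.8. The precision was lower here, with a median standard error of 0.092. The genes at the smallest adjusted p, picked after their values were seen, were mel1 (0.62 ± 0.11, SE), aes1 (0.55 ± 0.10), tms1 (0.45 ± 0.08) and mug184 (0.41 ± 0.07), each with adjusted p = 0.125. For none of these 2896 genes was the strain effect at 37 °C shown to differ from that at 25 °C. Among 2231 probe sets without a gene name, fitted and adjusted apart, 5 passed this test. Among the lists, 29 mating genes had a median difference of -0.098, with 22 below 0 (camera adjusted p = 0.00271), 16 iron genes -0.14, with 15 below 0 (camera adjusted p = 0.0144), and 46 ribosome biogenesis factors 0.024, with 32 above 0 (camera adjusted p = 0.0481), without a member past the test over all genes or adjusted over the list alone. Each of these calls was lost with an estimated correlation (adjusted p = 0.962). The mating call was also lost without replicate 3 of mis4-367 at 25 °C (adjusted p = 0.172). The iron call was lost without replicate 3 at 25 °C of mis4+ (0.0616) or mis4-367 (0.172), or at 37 °C replicate 2 of mis4+ (0.362) or 3 of mis4-367 (0.0992). The ribosome biogenesis call was lost without replicate 1 (0.118) or 3 (0.0616) of mis4+ at 25 °C, replicate 2 of mis4+ at 37 °C (0.362), replicate 3 of mis4-367 at 25 °C (0.245) or its replicate 1 at 37 °C (0.228), and with a block for culture (0.062). With 1 array left out the median of the mating list was from -0.188 (mis4-367 replicate 1 at 25 °C) to -0.032 (its replicate 3). It was -0.169 and -0.063 without replicates 2 and 3 of mis4+ at 37 °C, and -0.057 without replicate 1 of mis4-367. The ribosome biogenesis median turned to -0.003 without replicate 2 of mis4+ at 37 °C. It was 0.069 without its replicate 3, and 0.043 and 0.012 without replicates 2 and 3 of mis4-367 at 25 °C. None of the 32 subtelomeric genes passed over all genes; adjusted over the list alone, 3 had a higher and 2 a lower response in mis4-367.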

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

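Of the tests in this part, those of RNA degradation and of a swapped culture for the array that stood apart, that of the single array behind the larger count at 37 °C, and the list mean without that array, were chosen only after the result was seen.

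Of 29 mating and pheromone genes, 9 were lower in mis4-367 at 37 °C, with a list median of -0.25 (camera adjusted p = 3.43e-05, lost with an estimated correlation at 0.716). The list also differed in the test of the difference of temperature responses (camera adjusted p = 0.00271, 22 of 29 members below 0), a call lost with an estimated correlation (adjusted p = 0.962) and without replicate 3 of mis4-367 at 25 °C (adjusted p = 0.172). Without the array of mis4+ replicate 3 the median was -0.169 (camera adjusted p = 9.93e-06). The list mean was then -0.215 ± 0.057 (SE between arrays), against -0.253 ± 0.054 with it. Limits set for the median were -0.08 for that array as the sole source and -0.16 for its exclusion. The median passed the second limit by less than the SE of the mean, and lay within 2 SE of the first. The mean lay more than 2 SE below -0.08, a limit that was not set for it. That array as the sole source was thus argued against but not excluded, and it may account for part of the size. Probe sets shared between the M-factor genes were not the whole source, as the median without mfm1, mfm2 and mfm3 was -0.222 (camera adjusted p = 0.000145). Intensity-dependent normalization was argued against by a percentile of 0.01 among 10000 lists matched on mean level, the smallest percentile they can give. After quantile normalization the median was -0.165 (camera adjusted p = 0.000196), so part of the size depends on the scaling. That the thermosensitive loader lowers these genes is a hypothesis that stays open, found and tested on the same arrays, and so does a difference in the arrest. Of 26 markers of cells outside G1 (mitosis and septation), 5 were lower and 22 lay below 0, with a median of -0.15 (camera adjusted p = 0.0106, lost with an estimated correlation at 0.716), while the 19 MBF targets did not pass (camera adjusted p = 0.417), and whether the probe set of res1 reads the plasmid's fragment is not known here. The median of these markers was -0.089 without replicate 3 of mis4+ and -0.094 after quantile normalization. The gene-by-gene test of the difference between temperatures passed for none of the members.

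Replicate 3 of mis4+ at 37 °C stood apart from its group, with a median deviation of 0.101. A temperature response of larger or smaller extent was argued against by a correlation across genes of -0.023 between its deviation and the temperature effect in mis4-367. A longer or shorter exposure could change other genes than the effect at 2 h does, so this correlation cannot decide on it. RNA degradation would raise the 3' over the 5' signal of control transcripts, and on this array that difference departed by -0.249 from the other arrays of its group, the opposite direction. A mis4-367 culture under a wild-type label was argued against by r = -0.144 with the strain effect at 25 °C. The cause of this array's departure stays open, and no explanation beyond these was tested. The genes furthest from the group, picked after their values were seen, were rrn7 (-0.81), naa25 (-0.76), dic1 (0.72) and atg20 (0.68).

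In the fit with 1 spread for all groups, more genes changed between the strains at 37 °C (208) than at 25 °C (18). With only the compared groups in the fit the order turned, with 10 genes at 37 °C and 154 at 25 °C. Replicate 3 of mis4+ at 37 °C may account for the difference between 208 and 18: without it 103 genes changed at 37 °C and 102 at 25 °C in the same fit. That fit had 1 array less at 37 °C than at 25 °C, so its counts are not like for like. The median effect of the 208 genes was 0.29 with the array and 0.231 without it. These genes were picked in the fit with that array, so a smaller median without it is partly built in. No such median was computed for other arrays, so the drop cannot be ascribed to this array in particular. Other arrays moved the count as well: it was 195 and 566 without replicates 1 and 2 of mis4+ at 37 °C, and 121, 22 and 92 without replicates 1, 2 and 3 of mis4-367. Strain effects of equal size at both temperatures were not excluded, with a ratio of median effects of 1.39 with the array and 1.12 without it, and cannot be told apart from a larger effect at 37 °C because 1 array moves the ratio. A stronger loss of Mis4 function at 37 °C, the difference that the design names, stays open, and the test of the difference passed for 0 genes.

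Other splits of the arrays were too few for a share under 0.05, because 3 against 3 arrays make 10 splits and the smallest share they can give is 0.1. For the strains at 37 °C, the strains at 25 °C, the shift in mis4+ and the shift in mis4-367, the real split called 208, 18, 1601 and 1633 genes, 1 of 10 splits called as many, and the highest other split called 0. Each other split mixed arrays of both groups, so a difference between the groups widens its spread and lowers its calls. The 0 calls of the other splits are therefore no support for the real one. For the difference of temperature responses the real split called 0 genes, as did each of the 10 splits.

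The iron list (camera adjusted p = 0.0144) and the ribosome biogenesis list (camera adjusted p = 0.0481) also differed between the strains in their temperature response, with adjusted p = 0.962 for each with an estimated correlation.

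Probe sets with no gene name here, which the gene comparisons did not use, held signal as well. Of 2231 above the background level, 98 changed between the strains at 37 °C (29 higher, 69 lower), 30 at 25 °C (7 higher, 23 lower) and 5 in the difference of temperature responses (4 higher, 1 lower). These p-values come from a fit of the 2231 probe sets alone and are adjusted over them. At 37 °C the largest rise in mis4-367 among them was 1.36 ± 0.13 (SE, 2.57-fold, adjusted p = 7.47e-05) and the largest fall -1.73 ± 0.38 (3.31-fold, adjusted p = 0.0263), followed by -1.58 ± 0.19 (adjusted p = 0.000429).

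Control probe sets of S. pombe ribosomal RNA, which the gene comparisons did not use, were lower in mis4-367 at 37 °C in all 7 cases. Of these 3 had adjusted p under 0.05, adjusted over all 10928 probe sets. The 7 read parts of the 18S, 28S and 5.8S RNAs, so they are not independent. The largest difference was -1.84, for the 3' part of 18S RNA (limma, adjusted p = 0.0684). There mis4+ rose with the shift from 7.62 to 9.66 (SD 0.81), and mis4-367 stood at 7.64 and 7.82. At 25 °C 4 of the 7 were lower and 0 passed.

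Outside the gene comparisons as well, the control probe set for the 5' part of GPD3 rose by 3.14 on the log2 scale with the shift in mis4+ and by 3.09 in mis4-367, and 1 probe set for the middle part by 1.76 and 1.78. The other middle probe set (0.16 and 0.23) and the 3' probe set (0.16 and 0.13), both marked as shared between sequences, rose less. In mis4+ at 25 °C they were also brighter, at 13.26 and 12.55, against 9.04 for the 5' probe set and 10.95 for the first middle one. Position along the transcript, sharing between sequences and brightness are therefore mixed here.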

How the results depend on the processing

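Chosen after the data were seen were the tests with array weights, with unnamed probe sets joined, without the third arrays at 37 °C (also for the shared spread alone) and with corrected lists, and those that left out 1 array for the lists and the correlations of effects. Of the named genes' results under the alternatives, 3206 kept direction and side of the threshold, 188 lost and 13 gained a call and 1 reversed: tlh2 for the shift in mis4+, 0.36 as deposited and -0.19 after quantile normalization (adjusted p = 0.2). Of the list results 675 were the same, 67 lost and 21 gained a call, with no reversal. Except where a reason is given, the cause was not tested. The count for the strains at 37 °C (208) was 10 with only the compared groups, 474 with array weights, 97 without the third arrays of both strains at 37 °C, 7 and 1 with limits of 1.5-fold and 2-fold, and 22 to 566 with 1 array left out. At 25 °C (18) it was 3 after quantile normalization, 154 with only the compared groups, 496 with array weights, 46 with unnamed probe sets, 102 with the spread estimated without the third array of mis4+ at 37 °C, 2 and 1 with the fold limits, and 5 to 14 with 1 array left out. The shift gave 2842 (mis4+) and 2922 (mis4-367) with unnamed probe sets, since more probe sets were tested, 295 and 326 with 1.5-fold, 85 and 97 with 2-fold, and 1357 to 1734 and 1439 to 1581 with 1 array left out. The difference of responses gave 2 with array weights, 1 with unnamed probe sets, and 0 to 1 with 1 array left out (1 without mis4-367 replicate 2 at 25 °C). The subtelomeric exact test had p = 0.0328 at 25 °C after quantile normalization, when 3 genes passed in all, and for the shift in mis4+ p = 0.0822 with 20 genes per end and 0.149 after quantile normalization. With 1 array left out it ranged from 0.0238 to 0.378 for the strains at 37 °C, from 0.0541 to 0.144 at 25 °C, from 0.000102 to 0.00352 for the shift in mis4+ and from 0.0489 (without mis4-367 replicate 3 at 25 °C) to 0.375 in mis4-367. The correlation of strain effects ranged from 0.478 to 0.584 and that of temperature effects from 0.939 to 0.97. Without its 5 members of other known functions the ribosome biogenesis list had camera adjusted p = 0.00204 at 37 °C and 0.0169 for the difference of responses. Signal over background limited little, since 2879 of 2896 genes lay above it. The comparison of convergent genes was not run, as strands were not at hand.

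Replicate numbers do not pair the strains: deviations of same-numbered arrays had r of -0.38, 0.13 and -0.24 at 25 °C and -0.16, 0.18 and -0.06 at 37 °C. With the number as a replicate block 181 and 26 genes changed between the strains, 1587 and 1630 with the shift and 0 in the difference; subtelomeric p was 0.448, 0.252, 0.00216 and 0.209. With the culture, inferred from the numbers within a strain, as a block the shift changed 1534 and 1594 genes and the difference of responses 0.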

Other observations

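The tests of the averaged effect in this part were chosen after the data were seen.

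Averaging the strain effect over both temperatures, 375 genes differed between mis4-367 and mis4+, 307 lower and 68 higher, in a fit that took the arrays of a culture as independent. With the mean of each culture (inferred from the replicate numbers), 3 against 3, 264 genes differed (228 lower, 36 higher), and 238 of them were among the 375. The direction depended on the scaling, with 230 lower and 135 higher of 365 after re-centring, and 91 lower and 98 higher of 189 after quantile normalization. Both steps tend to even the directions by construction, so they cannot decide the direction. On the deposited scale, with arrays as independent, meiotic genes had 12 of 43 members lower and none higher, and mating genes 11 of 29, mitosis and septation genes 7 of 26, and heterochromatin and telomere silencing factors and core stress genes 5 each of 27 and 29. With culture means, 12 meiotic, 13 mating, and 7 mitosis and septation genes were lower. Of heterochromatin and telomere silencing factors 2 were lower, and of core stress genes 4, with none higher in these lists. After quantile normalization meiotic genes had 2 lower and 2 higher, mating genes 8 lower, mitosis and septation genes 5 lower, core stress genes 3 lower, and heterochromatin and telomere silencing factors 1 lower and 1 higher. The genes lowered most were str3 (-0.92 ± 0.17, SE, adjusted p = 0.00665), mel1 (-0.84 ± 0.06, adjusted p = 1.09e-05), mfm1 (-0.60), spn6 (-0.60), but1 (-0.59), mfm3 (-0.58), rec10 (-0.52), meu10 (-0.52), wtf20 (-0.47) and lsd90 (-0.45). Those raised most were tim10 (0.33 ± 0.09, adjusted p = 0.0308), sub1 (0.31), dss1 (0.31), aes1 (0.30) and res1 (0.28). Each of these 15 genes passed with culture means, and after quantile normalization rec10 (adjusted p = 0.0595), wtf20 (0.0585) and tim10 (0.0564) did not.

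Without replicate 3 of mis4+ at 37 °C, with arrays as independent, 436 genes differed (335 lower, 101 higher), and 343 of the 375 were among them. The real split of the cultures called 375 genes and the highest of the other splits 0. Of 10 splits 1 called as many, and 10 splits are too few for a share under 0.05. Each other split mixed cultures of both strains, so a strain difference widens its spread and lowers its calls, and the 0 calls are no support.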
